A study of Mus musculus with 11 samples.

How the data were processed

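Messenger RNA was measured in basal progenitors sorted by flow cytometry from the cortex of mouse embryos at embryonic day 13 (E13) and embryonic day 16 (E16). Basal progenitors are dividing cells of the developing cortex, away from the ventricular surface, that produce neurons. There were 6 arrays at E13 and 5 at E16, each a separate embryonic cortex, and the embryos of each stage came from 3 litters. The raw column label of every array ends in WT, which is read here as wild type. Which embryo came from which litter, and which marker the sort used, are not given in the sources used here. Per the labels' protocols, total RNA was extracted with the mirVana kit and biotin-labelled cRNA was prepared with the Illumina TotalPrep-96 kit before hybridisation to an Illumina bead array.

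The deposited table of raw probe intensities held 45281 probes per array on a linear scale. It was not normalized between arrays, and between 26.9% and 29.2% of the intensities of an array were below 0, so a background had been subtracted before deposit. The detection p-value of each probe on each array was deposited beside its intensity, per the file headers. The scanner software and its settings are not given in the sources used here. The deposited series value table held log2 values for 16554 probes, and each of those probes had a detection p-value under 0.05 on all 11 arrays. Another 54 probes that were detected on all 11 arrays had no value there, all of them among the 85 brightest. All 11 columns of that table held the same sorted values within a tolerance of 0.01, with a median of 8.22 and a range from 4.20 to 14.6 on the log2 scale, and each column had the rank order of the raw intensities of its array (lowest rank correlation 1). That table was used as an alternative only.

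Probes were named through a table of the array platform. Of the 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 were not listed and stayed unnamed here. Entrez identifiers of 34807 probes matched a gene table of assembly GRCm38.p6, which changed 0 symbols. Pou3f2 and Ddx3y had no named probe and were not analysed here.

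Raw intensities were background corrected with normexp, using the detection p-values, quantile normalized and taken to log2 after an offset of 16 (neqc in limma 3.58.1, run in R 4.3.3). A probe was kept when its detection p-value was under 0.05 on at least 5 arrays, the size of the smaller stage, which left 20599 probes, 17180 of them with a gene. For each gene the probe with the highest mean was tested, which gave 10568 genes. Several probes were kept for 4341 genes, and for 11 genes probes passed the test in opposite directions. Differences are E16 minus E13 on the log2 scale, from a linear model per gene with moderated variances and a mean-variance trend (lmFit and eBayes in limma). P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. These p-values treat the embryos as independent, although some share a litter. The number of arrays limits the precision, and the median standard error of a difference was 0.126 on the log2 scale. A gene detected on no array of a stage has only a bound there. It is given as "at least N-fold", the mean of the brighter stage against the dimmer stage's mean of, per array, the higher of the lowest detected signal and the gene's own value.

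The design, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The named genes were the 12 with the largest increases and the 12 with the largest decreases among those past the threshold whose arrays did not overlap between the stages, leaving out clone and predicted-gene symbols. They also included up to 4 past-threshold members of each list with the largest differences, or up to 2 as values where none passed, and genes named whatever their result, among them Eomes, Neurog2, Insm1, Pax6, Sox2, Tbr1, Bcl11b, Fezf2, Cux1, Cux2, Pou3f2, Ccnd1, Ccnd2, Hmga2, Lin28b, Nfia, Nfib, Xist, Ddx3y and Eif2s3y. An item of this rule is not reported here. Other genes that the text names were chosen after their values were seen.

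The 29 fixed lists covered markers of basal progenitors and radial glia, deep-layer and upper-layer neuron genes, pan-neuronal and synaptic genes, DNA replication, mitosis, G1 cyclins and kinases, kinase inhibitors, the Notch and Wnt pathways, let-7 targets and early temporal genes, chromatin regulators, gliogenic and astrocyte genes, axon guidance, area patterning, cytosolic ribosomal proteins, the mitochondrial respiratory chain, glycolysis, and immediate early and heat shock genes. Further lists held markers of other cells that a sort could carry: interneurons, Cajal-Retzius cells, the oligodendrocyte lineage, endothelium, mural and meningeal cells, microglia, red cells, and the choroid plexus and cortical hem. The 28 lists with at least 3 measured members were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with a correlation estimated for each list and with fry. Camera sets a list against the other genes, while fry sets it against no change, so a pass by fry answers a different question.

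On data simulated for the comparison of E16 with E13, with 10568 genes and the same numbers of arrays, 50 genes were changed at each of 4 sizes. Log2 changes of 0.5, 1, 2 and 3 were recovered for 58%, 92%, 100% and 100% of them, and 10 of 185 calls (5.41%) were false. In the same simulation 4 of 4 lists shifted by 0.5 were called, and 0 of 16 unshifted lists were. The simulated genes were independent of each other, while members of measured lists correlated (estimated at 0.341 for mitosis and 0.382 for replication). The simulation therefore does not show how often the list test makes false calls for such lists. A much smaller share of genes was changed in it than was called in the measured data (27.1%). Its adjusted threshold was thus stricter, and the recovered shares need not hold for the measured data. Values were simulated after normalization and filtering, so those steps were not tested.

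The alternatives chosen then were quantile normalization without background correction, cyclic loess, median centring, the authors' value table, no detection filter, detection at 0.01 on every array, every probe on its own, the mean of a gene's probes, no mean-variance trend, array weights, a threshold of 0.01, a test against a log2 difference of 0.5 (treat), the replicate number as a block, and each array left out in turn. A covariate for Xist level and fits without pairs of E16 arrays were chosen after seeing the data. Of the 462 possible splits of the arrays into groups of 6 and 5, 100 were drawn, the real one included, and each was tested in the same way.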

Results

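The transcriptome of sorted basal progenitors from mouse cortex was profiled at E13 (6 arrays) and E16 (5 arrays) to compare gene networks of this population early and late in cortical neurogenesis. Each array detected between 19731 and 20604 of 45281 probes (43.6% to 45.5%), with mean intensities between 349 and 481. Pearson correlations of normalized log2 intensity across genes lay between 0.982 and 0.994 among E13 arrays, between 0.979 and 0.991 among E16 arrays, and between 0.955 and 0.975 across the stages. The stages separated on the first principal component, which held 50.7% of the variance. The second component (10.8%) spread the E16 arrays from -18.8 to 21.8.

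**Figure D1:**
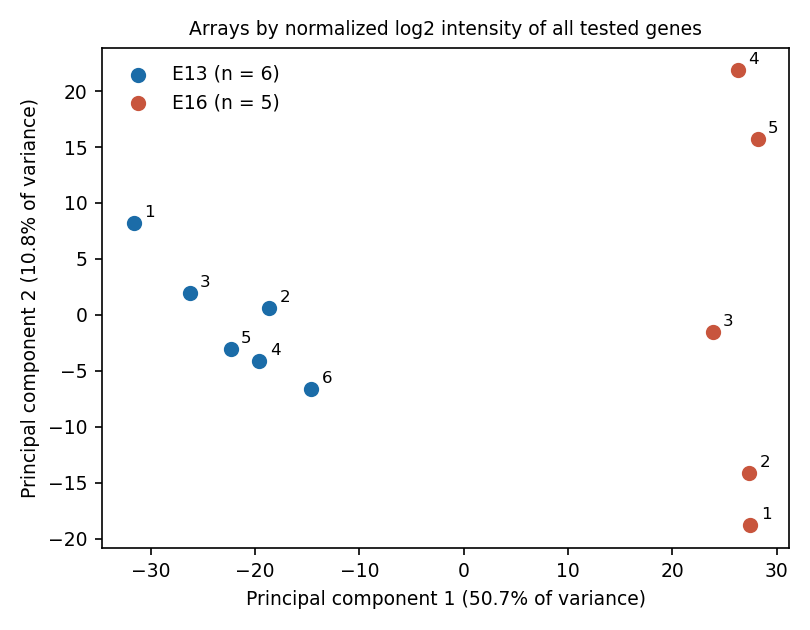
Scores of the 11 arrays on principal components 1 and 2 of normalized log2 intensity over all tested genes, with replicate numbers beside the points. E13 arrays lay between -31.6 and -14.6 on component 1 and E16 arrays between 23.8 and 28.2.

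At E16, 18 of 19 mitosis genes, 21 of 27 replication genes and 10 of 13 basal progenitor markers were lower than at E13, and 10 of 14 genes of upper-layer neurons were higher. Of 10568 genes tested, 1373 were higher and 1495 lower at E16 (27.1% in all, limma, adjusted p under 0.05). Centring each array on its median gave 966 higher and 1616 lower, so the higher share of changed genes was 37.4% in place of 47.9%. At least 2-fold changes were seen for 522 genes, 211 higher and 311 lower, and at least 4-fold changes for 29 higher and 36 lower genes. The arrays of the stages did not overlap for 1792 genes (17%), where chance gives 0.433% if the embryos are independent. Among 3419 detected probes without a gene name, 280 were higher and 245 lower. Of the 28 gene lists tested, 2 were higher and 8 lower at a preset correlation of 0.01, and 1 (upper-layer neurons) and 0 with an estimated correlation. Of 100 splits of the arrays, the real one included, 52 gave at least 2 lists higher and 4 gave at least 8 lower.

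The genes with the largest increases included a signalling adaptor, a transporter and a junction protein. Sla, a Src-like adaptor, was higher by 3.94 on the log2 scale (SE 0.431, adjusted p = 9.11e-06) and was detected on 4 of 6 E13 arrays. Pdzrn3, a ubiquitin ligase, rose by 3.65 (SE 0.255, adjusted p = 1.66e-07). Cldn3, a tight junction claudin, was detected on 0 of 6 E13 arrays and all 5 E16 arrays and was at least 9.36-fold higher at E16 (adjusted p = 8.15e-10). The bicarbonate cotransporter Slc4a4, detected on 3 of 6 E13 arrays, rose by 3.41 and the SH3-domain protein Sh3rf3 by 2.90. Bcl6, a transcriptional repressor that promotes neurogenesis, rose by 2.76. The other genes of this group were Ly6g6e (2.92), Inhba (2.64), Frmd6 (2.61), Rasgrf1 (2.50), Abcc8 (2.48) and Crym (2.48). Inhba and Crym were each detected on 5 of 6 E13 arrays.

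Of the 12 genes with the largest decreases, 6 encode transcription factors. Fezf1, a zinc finger factor, fell by 5.86 (SE 0.552, adjusted p = 2.32e-06). It was detected on all 6 E13 arrays and on 2 of 5 E16 arrays, replicates 3 and 4, at 7.93 and 7.23, while the other E16 arrays read between 4.62 and 4.71. Uncx, a homeobox factor, fell by 4.68 and was detected on 3 of 5 E16 arrays. Dlk1, an imprinted gene for a Notch-related membrane protein, fell by 4.81 (SE 0.320, adjusted p = 1.09e-07). Ccno, which acts in the formation of multiple cilia, fell by 3.73 and was detected on 4 of 5 E16 arrays. Dbx1, a homeobox gene of the pallial boundaries, and Lamp5 were detected on 0 of 5 E16 arrays and were at least 7.63-fold and 9.52-fold lower. Crabp2, a retinoic acid binding protein (-3.31), and Nxph1, which is also on the interneuron list (-2.90), fell, each detected on 2 of 5 E16 arrays. Ebf2 (-3.68), Lhx1 (-3.28) and Lhx5 (-2.98, detected on 2 of 5 E16 arrays) are also markers of Cajal-Retzius cells, early-born neurons of the marginal zone. Cdkn1a, a cell cycle inhibitor, fell by 2.93. Each of these 12 genes had its highest E13 value on replicate 1. That array also had the highest E13 means of the Cajal-Retzius (0.51), interneuron (0.77) and choroid plexus and hem (0.43) lists, relative to the E13 mean. At E16, Fezf1, Uncx, Dlk1, Nxph1, Ebf2 and Lhx5 were highest on replicate 3, as was the Cajal-Retzius list mean. The other genes of the 12 were highest on other E16 arrays. The cause was not tested.

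**Figure D2:**
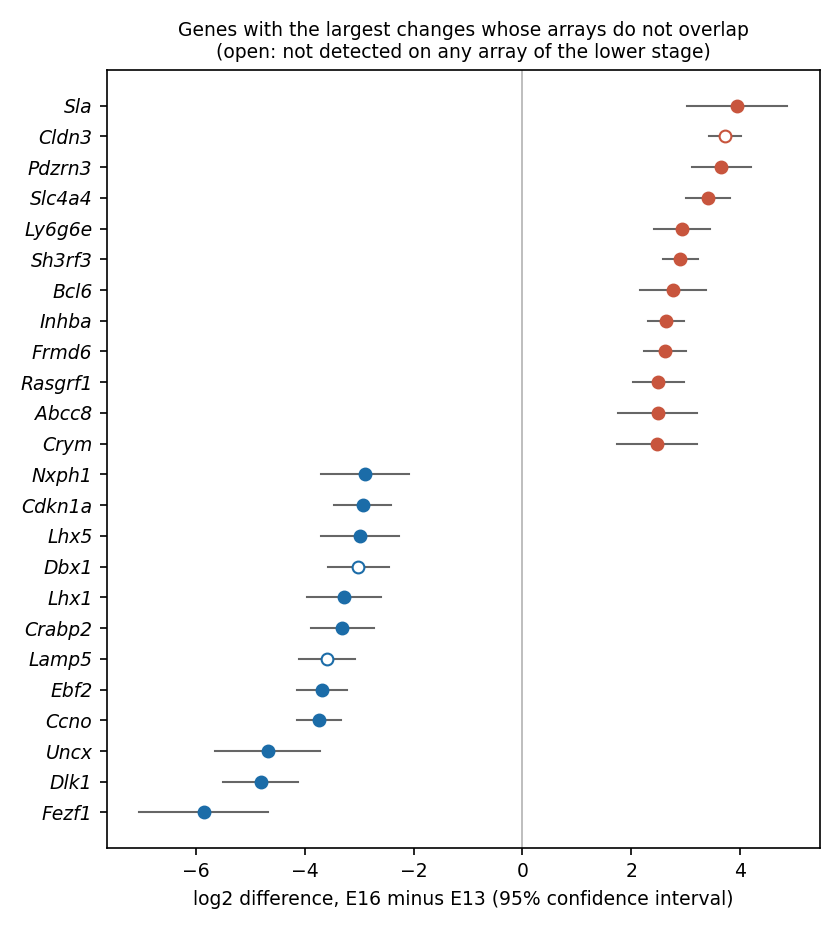
Log2 difference (E16 minus E13) and 95% confidence interval of the 12 genes with the largest increases and the 12 with the largest decreases among genes whose arrays did not overlap between 6 E13 and 5 E16 arrays, from 3.94 for Sla to -5.86 for Fezf1. Open points mark Cldn3, Lamp5 and Dbx1, which were not detected on any array of the lower stage, so that their points are fitted values and not bounds.

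Markers of basal progenitors were mostly lower at E16. Of 13 measured members 10 fell and 1 rose, with the same counts adjusted over the list alone, and the median was -0.75. The list fell with adjusted p = 7.18e-05 by camera, and adjusted p = 0.124 with an estimated correlation. Eomes, the transcription factor that marks this population, averaged 11.1 ± 0.264 (SD, n = 6) at E13 and 10.4 ± 0.327 (SD, n = 5) at E16, a difference of -0.75 (SE 0.15, adjusted p = 0.00176 in limma). The proneural factors Neurog2 (-0.60) and Neurog1 (-1.06, detected on 3 of 5 E16 arrays) and the Notch ligands Dll3 (-1.63) and Dll1 (-1.23) fell. Insm1, a zinc finger factor of basal progenitors, rose by 0.38 (adjusted p = 0.00305). The Cajal-Retzius list had a median of -2.50 in the same comparison and the erythroid list a median of 2.42.

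Radial glia markers, genes of the apical stem cells from which basal progenitors arise, went both ways. Of 22 members 5 rose, 8 fell and 9 did not pass, and 5 rose and 9 fell adjusted over the list alone. Slc1a3, a glutamate transporter, rose by 2.22 (adjusted p = 1.58e-08), Ptprz1, a receptor phosphatase, by 1.94 and Mfge8 by 1.21, while the intermediate filament gene Vim fell by 1.56. Sox2 differed by -0.23 (adjusted p = 0.438). Pax6 differed by 0.13 (adjusted p = 0.557), with its probe detected on 4 of 6 E13 and 3 of 5 E16 arrays. The list median was -0.24 and the list did not pass (adjusted p = 0.461). Its direction was down by camera and up by fry.

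Genes of DNA replication and mitosis fell together. In the mitosis list 18 of 19 members fell, 0 rose, and 19 fell adjusted over the list alone, with a median of -1.27. Plk1, named after its value was seen, differed by -1.98 (adjusted p = 0.0661). The spindle protein Nusap1 fell by 1.39 and Cdc20, an activator of the anaphase-promoting complex, fell by 1.39. Birc5, a member of the chromosomal passenger complex, fell by 1.37, and Ube2c, detected on 1 of 5 E16 arrays, fell by 1.40. The list passed with adjusted p = 7.39e-17 by camera, and adjusted p = 0.0864 with an estimated correlation. In the S phase list 21 of 27 members fell and 0 rose, 24 fell adjusted over the list alone, and the median was -0.57. Its adjusted p was 9.57e-11 by camera, and adjusted p = 0.159 with an estimated correlation. Among the members that fell were the ribonucleotide reductase subunit Rrm2 (-1.09) and the replication factors Mcm10 (-0.96) and Cdc45 (-0.86). Basal progenitor markers (median -0.75) and Cajal-Retzius markers (-2.50) were lower on the same arrays.

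**Figure D3:**
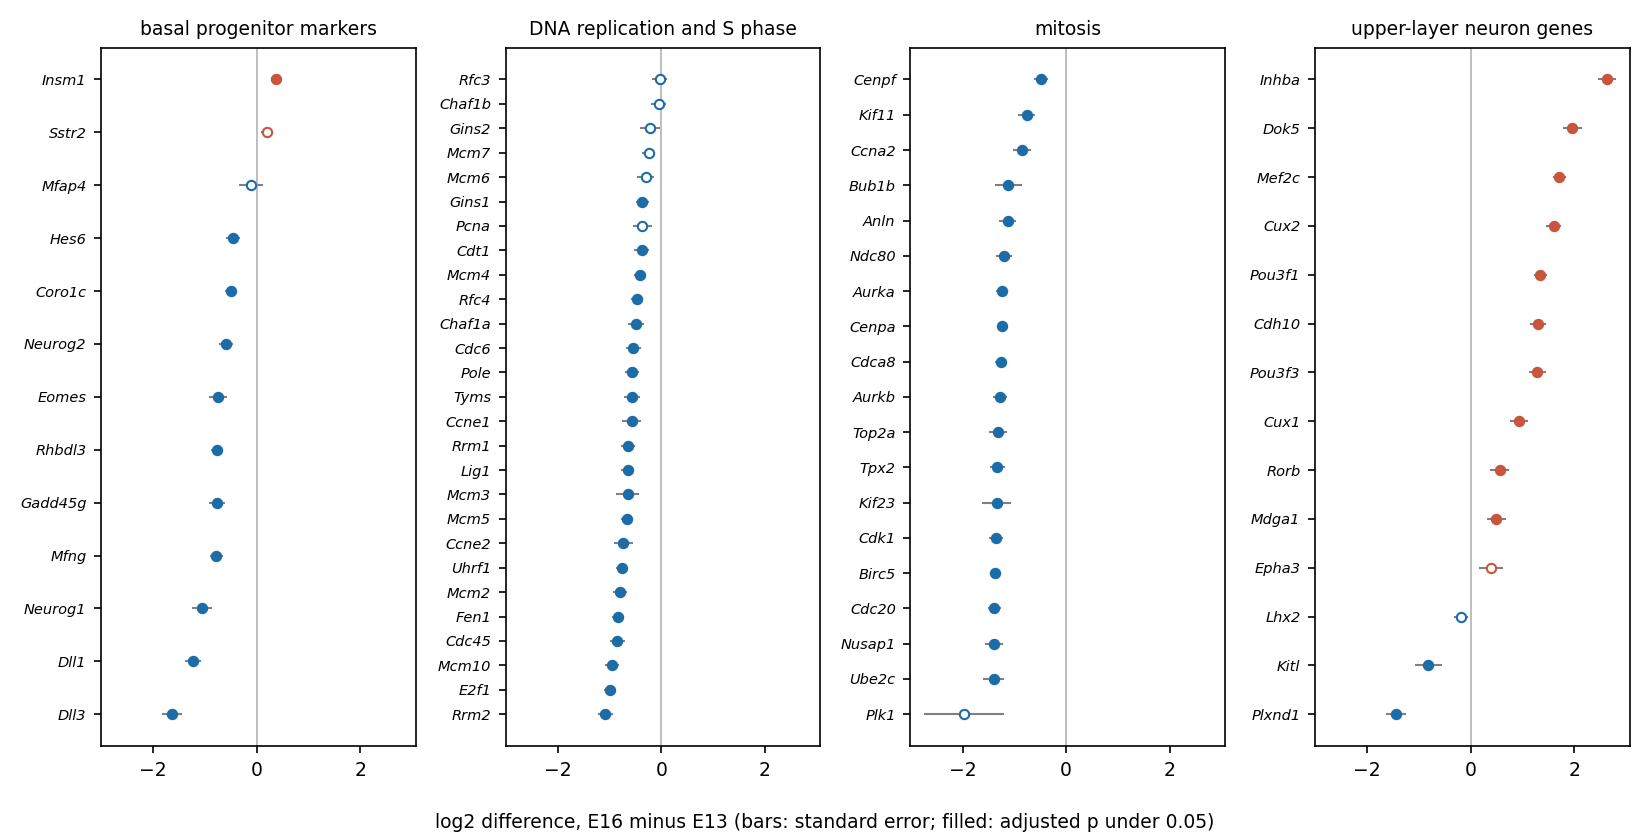
Log2 difference (E16 minus E13) with standard error of each measured member of 4 lists, from 6 E13 and 5 E16 arrays, with filled points for adjusted p under 0.05. In the mitosis list 18 of 19 members were lower and in the upper-layer list 10 of 14 were higher.

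Regulators of the G1 phase were lower in part. Of 12 members 6 fell and 1 rose, also adjusted over the list alone, with a median of -0.25 (adjusted p = 0.0250, and adjusted p = 0.319 with an estimated correlation). The list did not pass without E16 replicate 5 (adjusted p = 0.0511) or with array weights (0.0754). The D-type cyclin Ccnd1 fell by 1.39 (SE 0.173, adjusted p = 3.10e-05), and Rbl1, a relative of the retinoblastoma protein, fell by 0.70. Ccnd2 differed by -0.09 (adjusted p = 0.751). The kinase gene Cdk6 was detected on 0 of 6 E13 arrays and was at least 1.34-fold higher at E16.

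Some genes that restrain the cell cycle were lower as well. Of 11 kinase inhibitors and exit genes 5 fell and 1 rose, and 6 fell and 1 rose adjusted over the list alone, with a median of -0.45. Besides Cdkn1a (-2.93), the stress-response gene Gadd45a (-1.23), Cdkn1c (-1.14) and Cdkn2d (-0.46) fell. The list did not pass (adjusted p = 0.0614), though it did in 7 of 28 alternatives. These were no detection filter (0.0147), every probe on its own (0.00729), fry (2.05e-04), and the fits without E13 replicate 2 (0.0439), E16 replicate 1 (0.0398), E16 replicate 2 (0.0428) or both of these E16 arrays (0.0156).

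Genes of upper-layer neurons, which are born late, rose. Of 14 members 10 rose and 2 fell, also adjusted over the list alone, and the median was 1.11. This was the list whose call held with both correlations, with adjusted p = 4.84e-06 by camera, and adjusted p = 0.0142 with an estimated correlation. On the same arrays the Cajal-Retzius list had a median of -2.50 and the erythroid list one of 2.42. Inhba, an activin subunit, rose by 2.64, Dok5 by 1.96 and the transcription factor Mef2c by 1.71. The 2 that fell, Plxnd1 (-1.45) and Kitl (-0.82), are named after their values were seen. The homeobox factors Cux2 and Cux1 rose by 1.60 (SE 0.126, adjusted p = 4.82e-07) and 0.93 (SE 0.158, adjusted p = 4.61e-04).

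Genes of deep-layer neurons, which are born early, were lower as a list. Of 17 members 9 fell, 2 rose and 6 did not pass, with the same counts adjusted over the list alone, and the median was -0.34. The list passed with adjusted p = 0.00574 by camera, and adjusted p = 0.124 with an estimated correlation. On the same arrays the Cajal-Retzius list, which also marks early-born neurons, had a median of -2.50. The deep-layer list means were -0.11, -0.08 and -0.06 for E13 replicates 1 to 3 and 0.04, 0.12 and 0.08 for E13 replicates 4 to 6, relative to the E13 mean. The ETS factor Etv1 (-1.33) and the GATA cofactor Zfpm2 (-1.04) fell. So did the transcription factors Tbr1 (-0.78, adjusted p = 0.00185) and Bcl11b (-0.43, adjusted p = 0.0142). Crym and Ldb2 rose by 2.48 and 1.17. Fezf2, a determinant of subcerebral projection neurons, fell by 0.34 (adjusted p = 0.0361). It no longer passed when any of E13 replicates 3 to 6 or E16 replicates 3 to 5 was left out, with adjusted p between 0.0645 and 0.0905.

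**Figure D4:**
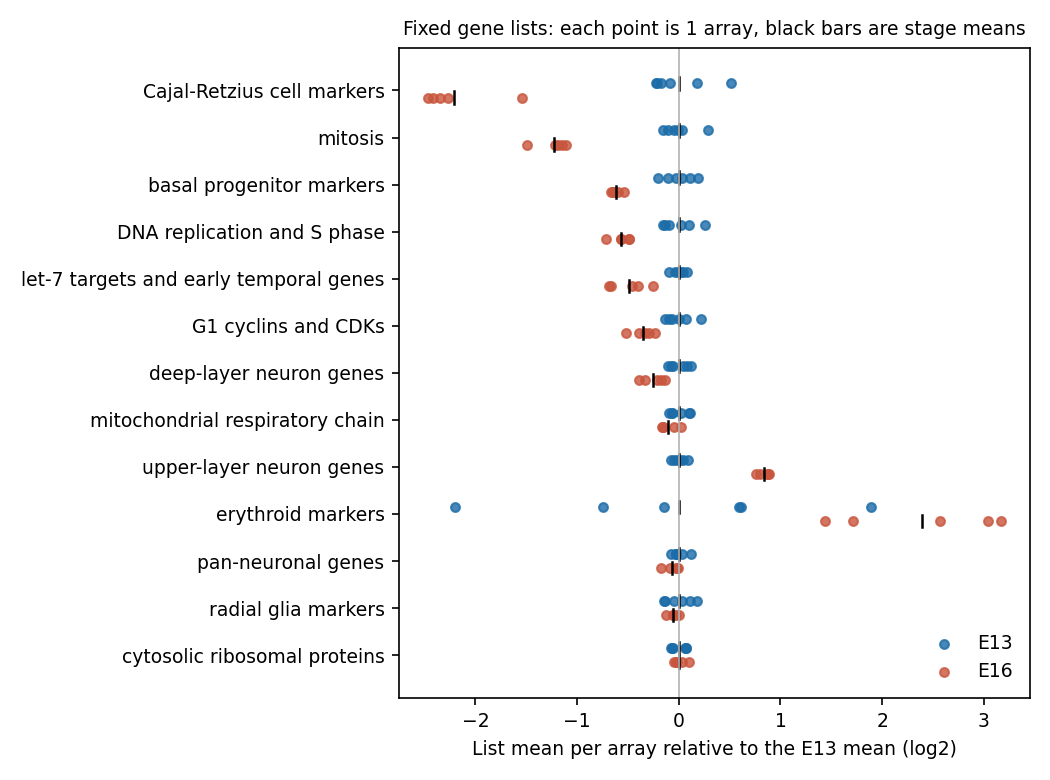
Mean log2 value of each list per array relative to the E13 mean, for 6 E13 and 5 E16 arrays, with black bars at the stage means. The mitosis mean of the E16 arrays lay between -1.49 and -1.11, and the erythroid mean spread from -2.20 to 1.89 among E13 arrays.

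Genes shared by all neurons did not pass as a group. Of 21 pan-neuronal genes 2 rose and 6 fell, also adjusted over the list alone. The median was 0.004, the mean -0.06 and the direction of the test down (adjusted p = 0.695). The intermediate filament gene Ina (-1.24) and Gap43, a growth cone protein (-0.70), fell, and the neuronal factor Myt1l rose by 0.94. Of 17 synaptic genes 3 rose and 5 fell, and 4 rose and 5 fell adjusted over the list alone (median 0.20, adjusted p = 0.536). The glutamate receptor genes Grin2b and Gria2 rose by 1.44 and 1.41, while the vesicular glutamate transporter Slc17a7 (-1.16) and the kainate receptor Grik2 (-0.77) fell.

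Genes of axon guidance and migration changed in both directions. Of 27 members 9 rose and 7 fell, 10 and 8 adjusted over the list alone, and the median was 0.27 (adjusted p = 0.102). The list passed without E16 replicate 4 (0.0448), with every probe on its own (3.77e-04) and with fry (0.00841). Sema3c, a secreted semaphorin, rose by 1.98 and Nrp1, a semaphorin receptor, by 1.75, while Sema6a fell by 1.32. The netrin receptor Dcc fell by 1.65 (adjusted p = 0.00162) with its brightest probe, and the probe left by detection at 0.01 on every array gave 0.14 (adjusted p = 0.638).

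Some RNA-binding proteins and other targets of the let-7 microRNA that mark early stages fell. Of 10 members 5 fell, 0 rose and 5 did not pass, and 7 fell adjusted over the list alone, with a median of -0.40 (adjusted p = 0.00244, and adjusted p = 0.230 with an estimated correlation). Lin28b, a repressor of let-7 processing, fell by 1.51 (SE 0.148, adjusted p = 3.50e-06) and was detected on 1 of 5 E16 arrays. The mRNA-binding protein Igf2bp1 (-0.82), Plagl2 (-0.75) and Igdcc3 (-0.73) fell. Cajal-Retzius markers (median -2.50) were lower and erythroid markers (median 2.42) higher on the same arrays. The 3 probes of Hmga2 were detected on 0 of 11 arrays.

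Genes linked to the later production of glia mostly rose one by one. Of 12 gliogenic and astrocyte genes 8 rose and 3 fell, 8 and 4 adjusted over the list alone, with a median of 0.54. The list did not pass (adjusted p = 0.0614), but did in 7 of 28 alternatives. These were median centring (0.0266), no detection filter (0.0171), every probe on its own (5.43e-05), fry (7.13e-05), and the fits without E13 replicate 6 (0.0434), E16 replicate 4 (0.0437) or E16 replicates 3 and 4 (0.0324). Its median was -0.32 in the authors' value table (adjusted p = 0.974). The nuclear factor Nfix rose by 1.56, Zbtb20 by 1.53 and Nfib by 0.44 (adjusted p = 0.00302), while the gap junction gene Gja1 (-1.57) and the glutamate transporter Slc1a2 (-1.28, detected on 3 of 5 E16 arrays) fell. Nfia differed by -0.32 (adjusted p = 0.0592). It passed without E13 replicate 1 (0.0229), without E16 replicate 2 (0.0279), or without both E16 replicates 1 and 2 (-0.47, 0.0143).

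Several transcription factors of cortical area patterning were lower. Of 11 members 5 fell and 1 rose, and 6 and 2 adjusted over the list alone, with a median of -0.42. The doublesex-related factors Dmrt3 (-1.73) and Dmrta2 (-1.07) and the nuclear receptor Nr2f2 (-1.44) fell. Etv5, a target of fibroblast growth factor signalling, was detected on 0 of 6 E13 arrays and was at least 2.67-fold higher at E16. The list did not pass (adjusted p = 0.0549), but did in 12 of 28 alternatives. These were median centring (0.0453), no background correction (0.0392), the authors' value table (median -0.68, 0.00166), no detection filter (0.0147), detection at 0.01 on every array (median -0.67, 0.00139), fry (1.53e-04) and the Xist covariate (0.0465). It also passed without E13 replicate 4 (0.0364) or 5 (0.0398), E16 replicate 1 (0.0301) or 2 (0.0461), or both of these E16 arrays (0.0222).

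In the Notch pathway, which keeps progenitors undifferentiated, 6 of 18 members fell and 2 rose, also adjusted over the list alone (median -0.17, adjusted p = 0.142, and 0.00398 by fry). Besides Dll3 and Dll1, the target gene Hey1 fell by 1.38, and the modulator Dtx1 rose by 0.85. In the Wnt pathway 5 of 22 members fell and 2 rose, 6 and 2 adjusted over the list alone (median -0.04, adjusted p = 0.459, and 0.00172 by fry). The repressor Tcf7l1 (-2.35), the ligand Wnt7a (-1.60) and the feedback inhibitor Nkd1 (-1.10) fell, and Dkk3 rose by 1.29. The Wnt median was 0.05 in the authors' value table. Of 23 chromatin regulators 3 rose and 2 fell, also adjusted over the list alone (median -0.09, adjusted p = 0.763). Hmgb2, a chromatin protein of proliferating cells, fell by 1.22, and the remodelling subunit Smarcd3 rose by 0.48.

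Cytosolic ribosomal protein genes did not pass as a group. Of 51 members 2 rose and 2 fell, 0 and 1 adjusted over the list alone, with a median of 0.02 (adjusted p = 0.483) that became -0.06 with median centring. The largest difference was that of Rps4l, which fell by 1.2. Most respiratory chain genes did not pass, while the list was lower by camera. Of 65 members 5 fell and 0 rose, 4 fell adjusted over the list alone, and the median was -0.11 (adjusted p = 0.0250, adjusted p = 0.125 by fry, and adjusted p = 0.612 with an estimated correlation). Relative to the E13 mean, the list means were 0.11, 0.02 and 0.10 for E13 replicates 1 to 3, -0.10, -0.07 and -0.07 for E13 replicates 4 to 6, and between -0.17 and 0.02 at E16. This list did not pass when any of E13 replicates 1 and 3 or E16 replicates 1, 2 and 3 was left out, with adjusted p between 0.0536 and 0.0802, or without both E16 replicates 1 and 2 (median -0.06, 0.176). The NADH dehydrogenase genes Ndufv3 (-0.49) and Ndufc1 (-0.26) fell. Of 16 glycolysis genes 3 rose and 3 fell, also adjusted over the list alone (median -0.12, adjusted p = 0.695). The neuronal enolase Eno2 rose by 0.76 and the lactate dehydrogenase subunit Ldhb by 0.70, and phosphoglycerate kinase, Pgk1, fell by 0.68.

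Markers of Cajal-Retzius cells were the other-cell list with the largest decrease. Of 7 measured members 6 fell and 0 rose, also adjusted over the list alone, with a median of -2.50 (adjusted p = 4.84e-06, and adjusted p = 0.124 with an estimated correlation). Ebf3, a helix-loop-helix factor, fell by 2.50 beside Ebf2, Lhx1 and Lhx5. E16 replicate 3 had the highest list mean of its stage (-1.54 against -2.27 or lower), relative to the E13 mean.

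The erythroid list rose. All 3 of its measured members, the haemoglobin genes Hba-a1 (2.48), Hbb-bt (2.42) and Hbb-bs (2.26), passed, also adjusted over the list alone, although their values overlapped between the stages. Its adjusted p was 0.0250 by camera, 0.0878 with array weights, and adjusted p = 0.360 with an estimated correlation. The median was 0.38 with no detection filter. Hba-a1 was detected on 5 of 6 E13 arrays and ranged from 5.08 to 9.55 at E13 and from 9.22 to 11 at E16.

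**Figure D5:**
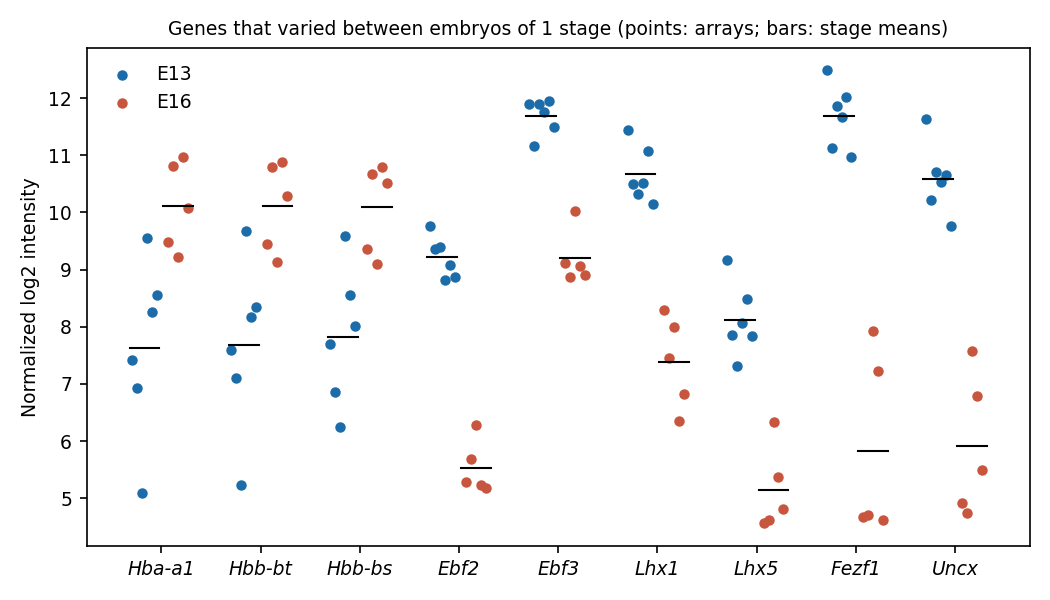
Normalized log2 intensity of 9 genes on each of 6 E13 and 5 E16 arrays, with black bars at the stage means. The haemoglobin gene Hba-a1 spread from 5.08 to 9.55 at E13, and Fezf1 was at 7.93 and 7.23 on 2 E16 arrays and between 4.62 and 4.71 on the others.

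Interneuron and ventral forebrain markers included 3 genes that fell and 1 that rose of 8, also adjusted over the list alone (median -0.14, from -0.41 to 0.02 over the alternatives, adjusted p = 0.459). Beside Nxph1, the neuropeptide gene Sst, detected on 5 of 6 E13 and 2 of 5 E16 arrays, fell by 1.28, while Gad2, an enzyme of GABA synthesis, rose by 0.77. Of 4 choroid plexus and hem markers 2 fell and 0 rose, and 3 fell adjusted over the list alone (median -0.55, from -1.44 to -0.09 over the alternatives, adjusted p = 0.146, and 0.0112 by fry). These were Rspo2 (-0.80, detected on 2 of 5 E16 arrays) and Lmx1a (-0.62, 1 of 5). In the oligodendrocyte lineage list 1 of 4 members rose, also adjusted over the list alone (median 0.01, adjusted p = 0.483, and 0.0339 by fry). This was Olig1, higher by 1.32 and detected on 2 of 6 E13 arrays. Of 4 endothelial markers 1 rose, also adjusted over the list alone (median 0.04, adjusted p = 0.483, and 0.0108 by fry). This was Ramp2, by 0.69. Both medians were below 0 with median centring, at -0.05 and -0.03. None of the 3 microglia markers passed, also adjusted over the list alone (median 0.12, adjusted p = 0.536), with Aif1 at 0.16 and Ctss at 0.12. No mural or meningeal marker of 11 was measured above the detection filter.

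Immediate early and heat shock genes, which respond to handling, went both ways. Of 10 members 3 rose and 2 fell, 5 and 2 adjusted over the list alone (median 0.29, adjusted p = 0.30, and 0.0431 without E16 replicates 3 and 4). Fos rose by 1.55 (adjusted p = 0.0200), with E16 replicates 1 and 2 at 8.99 and 9.39 and the other E16 arrays between 6.45 and 7.65. It did not pass without E16 replicate 1 (0.0575) or E16 replicate 2 (0.0525), and without both, a choice made after seeing the data, the difference was 0.67 (adjusted p = 0.153). Ier3 rose by 0.83 and the chaperone Hsph1 fell by 0.50. Xist is the RNA that coats the inactive X chromosome. The mean of its 4 probes was high on 3 of 6 E13 arrays and 4 of 5 E16 arrays (9.49 to 11.1) and low on the others (4.55 to 4.62). The tested Xist probe differed by 2.57 (adjusted p = 0.254), and by 3.95 without E16 replicate 4 (adjusted p = 0.0475). The tested probe of the Y-linked gene Eif2s3y differed by 0.07 (adjusted p = 0.846). Its other probe was high on the 4 arrays low in Xist (9.70 to 10.2) and low on the other 7 (4.34 to 4.51). Xist and this probe thus followed embryo sex, which is not given in the sources used here and was uneven between the stages. The Xist differences above are therefore not read as a change with stage.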

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

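The tests of dilution, scaling, marker correlation and haemoglobin correlation below were chosen after the results they bear on were seen. In each stage the gap between the highest or lowest array and its nearest neighbour, as a share of the stage's whole range, was set against Dixon's 95% critical value for named genes, list means and array measures. This singled out 18 of 320 tests (5.62%), and chance does so in about 1 in 20. E16 replicate 4 held 6 of the 18 values.

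E13 replicate 3 stood above the other E13 arrays for Birc5 (gap share 0.772), E2f1 (0.831) and E2f2 (0.672). E13 replicate 1 stood below the others for Gria2 (0.683) and Ptprz1 (0.701), and E13 replicate 6 above them for Inhba (0.659). At E16, replicate 4 was the highest for Eno2 (0.850) and Rps4l (0.714), and the lowest for Cdk6 (0.777) and Xist (0.772). It was the only E16 array low in Xist, which followed embryo sex. It was also the lowest for the means of the synaptic list (0.746) and the mitosis list (0.71). E16 replicate 3 was the highest for Ebf3 (0.793), Mcm10 (0.739) and the mean of the Cajal-Retzius markers (0.789). E16 replicate 1 was the highest for Cux2 (0.808). E16 replicate 5 was the lowest for Sox2 (0.809) and for mean intensity (0.715), at 349 against 392 for the next array.

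Mitosis genes had a median of -1.27 and replication genes one of -0.57. The choice among scalings moved the mitosis median little, since its value nearest to 0 under the other scalings and in the authors' values was -1.25. Each of these scalings aligns the arrays with each other, so a shift of all genes between the stages could not show and was not tested. The mitosis mean fell further than the marker mean by -0.61 (95% interval -0.80 to -0.42, two-sided exact permutation p = 0.00216, the smallest that the 462 splits can give), and the replication mean differed from it by 0.054 (interval -0.09 to 0.20, exact p = 0.420). The basal progenitor markers went from -1.63 to 0.38 (mean -0.62, SD 0.552), so they did not measure the share of basal progenitors closely enough, and dilution by other cells cannot be told apart from a change within the progenitors for either list. Marker RNA carried into young neurons and a change of the cell cycle with stage stayed open as well.

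Cajal-Retzius markers had a median of -2.50, and the median nearest to 0 under the other scalings and in the authors' values was -2.47. The choice among these scalings thus moved it little, and a shift of all genes between the stages was not tested here either. With the stage means removed, the 7 markers had a mean pairwise correlation of 0.306 over the arrays, above that of 99.5% of 10000 random lists of similar mean level (median -0.01, 95th percentile 0.162). A share of Cajal-Retzius cells that varies between embryos of a stage may contribute, with E13 replicate 1 (0.51) and E16 replicate 3 (-1.54) the highest list means of their stages. The correlation cannot tell this from markers regulated together, since the interneuron (0.479), replication (0.382) and mitosis (0.341) lists had higher correlations. E13 replicate 1 also had the highest E13 means of the interneuron (0.77) and choroid plexus and hem (0.43) lists. Ebf3 averaged 11.7 at E13 and 9.20 at E16, no marker is on another fixed list, and how far the sort removes these cells is not given in the sources used here. A change in these genes within the progenitors with stage stayed open and was not tested.

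The haemoglobin genes had a median of 2.42 and spread widely within each stage. With the stage means removed, the alpha gene Hba-a1 and the beta gene Hbb-bs correlated over the 11 arrays at r = 0.941 (permutation p = 8.0e-05) and rho = 0.882 (p = 0.00076), and at r = 0.898 without the 2 arrays farthest from the median. Hba-a1 and Hbb-bt, the other of 2 pairs tested, gave r = 0.994 and rho = 0.964, each with permutation p = 1e-05, the smallest that can be given, and r = 0.981 without 2 arrays, and adjustment over the pairs left p at 8.0e-05 and 2.0e-05 for r. Red cell RNA carried into the sorted cells may account for this pattern, and of the other red cell genes Alas2 and Slc4a1 were each detected on 0 of 6 E13 and 1 of 5 E16 arrays, Hbb-b2 on 0 and 3, Hbb-y on 1 and 0, and Hbb-bh1 and Hba-x on 0 and 0. Haemoglobin transcription within the progenitors stayed open and was not tested.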

How the results depend on the processing

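The Xist covariate and the fits without 2 E16 arrays were chosen after seeing the data. In every alternative the genes called both there and in the reported fit went the same way. This could not come out otherwise without the mean-variance trend, at a threshold of 0.01, with treat, with the estimated correlation or with fry. These use the same differences as the reported fit. With every probe on its own, only the brightest probe of each gene was compared, although for 11 genes probes passed in opposite directions. The counts of genes higher and lower stayed within 1.5 times the reported 1373 and 1495 except at a threshold of 0.01 (812 and 949) and in a test against a log2 difference of 0.5 (treat, 200 and 293), which both ask for more by construction. Genes changed at least 2-fold fell to 343 when detection at 0.01 on every array was required, where 8427 genes were tested, and numbered 783 with quantile normalization without background correction. Leaving out 1 array gave 1177 to 1345 higher genes, 1278 to 1520 lower genes, 488 to 549 genes changed 2-fold, 2 to 4 lists higher (4 without E16 replicate 4) and 7 to 9 lists lower. Lists higher numbered 1 in the authors' value table, with detection at 0.01 on every array, with array weights and at a threshold of 0.01, 4 with every probe on its own, 4 without E16 replicates 3 and 4, and 6 with fry. With camera and an estimated correlation 1 list was higher and 0 were lower. The cause was not tested for these lists. The upper-layer list passed in all 28 alternatives, and the mitosis, replication, basal progenitor, Cajal-Retzius, deep-layer and let-7 lists in 27 of 28, all but the estimated correlation. Without a detection filter the median was 0.38 for the erythroid (2.42 reported), -1.57 for the Cajal-Retzius (-2.50) and -0.22 for the let-7 list (-0.40), and with every probe on its own 0.69 for the upper-layer list (1.11). The G1 median was -0.46 in the authors' value table and -0.40 with detection at 0.01 on every array (-0.25 reported). Among lists that did not pass, medians that moved by over 1.5 times or changed sign ranged from -0.44 to -0.15 (radial glia), -0.07 to 0.07 (pan-neuronal), 0.09 to 0.26 (synaptic), -0.22 to 0.001 (Notch), -0.10 to 0.09 (Wnt), -0.13 to -0.02 (chromatin), -0.32 to 1.11 (gliogenic), -0.68 to -0.31 (area patterning), -0.06 to 0.05 (ribosomal), -0.18 to -0.07 (glycolysis), 0.15 to 0.45 (immediate early), -0.41 to 0.02 (interneuron), -0.09 to 0.06 (oligodendrocyte), -0.03 to 0.10 (endothelial), 0.02 to 0.26 (microglia) and -1.44 to -0.09 (choroid plexus and hem). The respiratory chain list was lost in 9, the G1 list in 4 and the erythroid list in 3 of 26. Among 130 named genes, Egr3 reversed from -1.01 to 0.46 without background correction and Dcc from -1.65 to 0.14 with detection at 0.01 on every array, where another probe was tested. The cause was not tested for Egr3, which was detected on 1 of 5 E16 arrays. Without E16 replicates 1 and 2 there were 1174 higher and 1189 lower genes, without E16 replicates 3 and 4 there were 1013 and 1243, and with the Xist covariate 1278 and 1402. Replicate numbers do not pair the embryos: arrays of the same number had correlations of deviations between -0.10 and 0.14, and 0 of 5 were closest to their own number. The fit with the replicate number as a block gave 1161 higher and 1279 lower genes, 544 changed 2-fold, 2 lists higher and 8 lower, and 6 named genes no longer passed. The bead chip as a block was not run, since chips are not given in the sources used here, and so whether chip and stage coincide, which would confound every difference, was not tested. Signal over background limits genes near the detection floor, such as Pax6 and Hmga2, whose differences cannot be excluded here.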

Other observations

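All gene groups and genes in this part were chosen after their values, or those of related genes, were seen, while the splits of the arrays were fixed beforehand. Some genes of multiciliated cell differentiation were lower, with Ccno alone among the 12 largest decreases. Ccno (-3.73, detected on 4 of 5 E16 arrays), its transcriptional regulator Mcidas, the dynein light chain gene Dynlrb2, Efcab1, the radial spoke gene Rsph1 and Mlf1 (-1.38) prompted a wider list. Of these Mcidas, Dynlrb2, Efcab1 and Rsph1 were detected on 6 of 6 E13 and 0 of 5 E16 arrays, and Mcidas was at least 3.08-fold lower at E16, Dynlrb2 at least 2.68-fold, Efcab1 at least 2.88-fold and Rsph1 at least 1.67-fold. Of 31 further members that had not been seen before, 10 fell, 1 rose and 20 did not pass, with a median of -0.25 (camera adjusted p = 0.00711, and adjusted p = 0.0671 with an estimated correlation). Among them Rfx2, a regulator of ciliary genes, fell by 1.10 and Plk4, a centriole duplication kinase that also acts in dividing cells, fell by 1.04. Foxj1, a regulator of motile cilia, differed by -0.24 (adjusted p = 0.285). Cajal-Retzius markers (median -2.50) were lower on the same arrays. Choroid plexus and hem markers had a median of -0.55 there, though that list did not pass (camera adjusted p = 0.146).

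Replication-dependent histone genes, whose transcripts accumulate in S phase, were lower. H4c6 (-1.53), H4c9 (-1.49), H4c18 (-1.45), H4c17 (-1.44), H3c7 (-1.36), H3c1 (-1.34), H3c6 (-1.32) and H4c1 (-1.27) prompted the list. Of 37 further members 28 fell and 0 rose, with a median of -0.58 (adjusted p = 2.46e-12, and adjusted p = 0.0671 with an estimated correlation). These genes are near-identical copies, so their probes may read one another. Whether fewer cells in S phase at E16 account for the shift was not tested.

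Imprinted genes of the Dlk1 cluster that had been seen to fall were Dlk1 (-4.81), Meg3 (-1.34) and Rian (-1.73, detected on 4 of 5 E16 arrays). Other members of the cluster were not counted, so whether the cluster moved as a whole was not tested. Outside the cluster Rasgrf1 (2.50) and Cdkn1c (-1.14) had been seen before and were not counted. Of 27 further imprinted genes that had not been seen before 7 fell and 2 rose, with a median of -0.16 (adjusted p = 0.0637, and adjusted p = 0.0671 with an estimated correlation). Grb10 (-1.19), Nnat (-1.01) and Ndn (-0.85) fell, and Nap1l5 (0.81) and Ppp1r9a (0.62) rose, so whether imprinted genes beyond the cluster moved as a set could not be decided.

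Of 166 families of genes grouped by symbol 4 passed by camera, and 0 with an estimated correlation. Semaphorin genes were higher, with 8 that rose and 1 that fell of 14 and a median of 0.59 (adjusted p = 0.0205, and adjusted p = 0.726 with an estimated correlation). The Mcm (5 of 8 fell, median -0.54, adjusted p = 0.0205), Cdc (9 of 29, -0.16, adjusted p = 0.0205) and Cdkn families (4 of 8, -0.36, adjusted p = 0.0379) were lower, with 0 that rose. The Cdkn family shares members with the list of kinase inhibitors and exit genes, which did not pass. All 5 Mcm genes that fell are also on the replication list. The Cdc family shares Cdc45 and Cdc6 with that list and Cdc20 with the mitosis list. These families are therefore not results separate from those lists.

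Ribosomal protein list means of the E13 arrays lay at 0.07, 0.06 and 0.07 for replicates 1 to 3 and at -0.07, -0.06 and -0.07 for replicates 4 to 6, relative to the stage mean. In all 11 of 28 lists were divided in this way. Among them were the replication (0.02, 0.10 and 0.26 against -0.15, -0.13 and -0.09), G1 (0.003, 0.07 and 0.22 against -0.14, -0.09 and -0.07), deep-layer (-0.11, -0.08 and -0.06 against 0.04, 0.12 and 0.08) and respiratory chain lists (0.11, 0.02 and 0.10 against -0.10, -0.07 and -0.07). The others were the area patterning, Notch, Wnt, radial glia, synaptic and erythroid lists. The other 9 ways to divide these arrays 3 against 3 did so for 0 to 9 lists, with 9 for replicates 1, 4 and 5 against the rest. By construction each of the 28 lists is divided by exactly 1 of all these ways. The division of replicates 1 to 3 against 4 to 6 follows the order of the sample numbers in the column labels. What that order stands for is not given in the sources used here. The cause was not tested.

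Chance can be excluded for the counts of changed genes if the embryos are taken as independent. Of 100 splits of the arrays 1, the real one, gave as many higher genes (1373, highest other 897), as many lower genes (1495, highest other 725) and as many genes changed 2-fold (522, highest other 369). The 2 other splits with many calls kept all E16 arrays together with 1 E13 array, a structure that follows stage. These splits do not bear on an effect of the bead chip, which was not tested. They exchange single embryos, although the embryos of each stage came from 3 litters, so chance differences between litters cannot be excluded. For the 8 lists lower, 4 of 100 splits reached that number at the preset correlation (highest other 11). The 3 others of these had 0 changed genes. This count took 1 direction only, although the direction of a drawn split is arbitrary, and other splits gave 8, 8 and 10 lists higher. Counted in either direction, more than 5 in 100 splits reached 8 lists, so chance cannot be excluded for this number. With an estimated correlation 0 lists were lower in the real split. Chance cannot be excluded for the number of lists higher, since 52 of 100 splits reached 2 (highest other 10). This count does not test either list by itself. The upper-layer list means lay between -0.07 and 0.09 at E13 and between 0.76 and 0.89 at E16, relative to the E13 mean.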
